A study of Drosophila melanogaster with 4 samples.

How the data were processed

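Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done with an antibody called wa191 against HP1a, in nuclei from wild-type Oregon-R Drosophila melanogaster larvae of the third instar. The labels give 4 libraries, which are 2 HP1a ChIP libraries (replicates 1 and 2) and 2 input libraries (replicates 1 and 2). Per the labels' protocols, tissue was homogenised and fixed with formaldehyde, chromatin was sheared by sonication, and bound chromatin was recovered on a protein A support. Nothing in the labels says whether the replicates came from separate collections of larvae, so the spread between them may be technical.

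The deposited files are 3 lists of enriched clusters, 1 for each ChIP library and 1 for the series as a whole. Per the labels, each input served as the background of the ChIP library with the same replicate number. The inputs entered the work only through those lists, so no library was compared with its input here. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The program that called the clusters, its threshold, and the way the replicates were combined into the series list are not given in the sources used here. Coordinates are those of FlyBase release 5, per the file headers, counted from 1, and sequence lengths were taken from the same headers. The headers also list the sequence Uextra, on which none of the 3 lists has a cluster.

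Each cluster carries 1 value, which is the authors' own. The deposited values are read here as log2 enrichment of ChIP over input. No header names their unit, and the reading rests on the values, whose repeats mostly differ by the log2 of small whole-number ratios. The values were used to describe, rank and filter clusters within a list and to compare clusters paired across replicates, and their repeats were tested for small whole-number ratios. The number of reads behind a library or a cluster is unknown, so no counting interval is given, and precision was judged from the 2 replicates.

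Chromosome sequences were put in 5 classes before the data were examined. These were the major arms (2L, 2R, 3L, 3R and X), chromosome 4, assembled heterochromatin (2LHet, 2RHet, 3LHet, 3RHet and XHet), Y (YHet) and unplaced sequence (U). As first laid out, unplaced sequence also held Uextra (29.0 Mb), on which no list has a cluster. Uextra was left out of the class, so unplaced cover is that of U alone and would be lower with Uextra. The covered share of a sequence is the length under clusters, with overlapping clusters merged, divided by the length in the header. The proximal part of a major arm was the 2 Mb of its sequence nearest the centromere. The centromere lies at the high coordinates of 2L, 3L and X and the low coordinates of 2R and 3R. Covered shares were also computed in bins of 500 kb, and of 100 kb on chromosome 4. The extent of a proximal block was read as the run of 100 kb steps from the proximal end that were at least 50% covered in both replicates, a rule chosen after seeing the data. A last step shorter than 50 kb was passed over.

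Replicates were compared by the share of clusters that overlapped the other list by at least 1 bp and by the base pair Jaccard index (shared over combined length). Both were tested with a one-sided permutation test of 1000 circular shifts of a list within each sequence, whose smallest p is 0.000999. The parts of the genome were tested as a family of 11 with Benjamini-Hochberg adjustment. Values of clusters paired across replicates were compared by the Spearman correlation and Pearson's r with two-sided permutation tests of 100000 resamples, across clusters, which are not independent replicates. The shift test was tested on simulated lists on 2L. For 100 pairs of unrelated lists of 250 clusters, the permutation p was below 0.05 in 2. For a pair with 100 planted shared clusters, the overlap of 44.6% equalled a direct count on the same lists, which checks the code alone. The permutation p of that pair was 0.0099, the smallest that 100 shifts can give. The simulated clusters were narrow and placed at random, with no proximal block. The check therefore does not cover lists that share regional density but not sites. For the part outside the proximal 2 Mb, shifts ran over the whole arm, including the emptied window. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

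Alternatives were clusters at or above the median value of their list, joining of clusters within 1 kb, leaving out unplaced sequence, a 50% overlap, major arms only, windows of 1 Mb and 5 Mb, the series list, and leaving out either replicate. Tests on genes were also laid out, with 10 gene lists and the share of cover in exons, introns and promoters. They were not made, because the gene table used here is on Release 6 and coordinates of different builds were not mixed. The rule for named items was therefore reduced to its part on clusters, the 3 widest of each replicate. Other regions named in the text were chosen after their values were seen.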

Results

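HP1a is a chromodomain protein that binds methylated lysine 9 of histone H3 and is a main structural protein of heterochromatin. The series mapped where it sits on the genome of whole Drosophila larvae, with 2 ChIP libraries, each called against its own input. Replicate 1 had 3110 enriched clusters that covered 19.1 Mb, and replicate 2 had 3052 that covered 20.4 Mb. That was 13.7% and 14.6% of the sequence length without Uextra. The median cluster was 2388 bp wide in replicate 1 and 2519 bp wide in replicate 2, and the narrowest was 1301 bp in both. The widest reached 117 kb in replicate 1 and 159 kb in replicate 2. Read numbers per library are unknown, so the spread between the 2 replicates is the only measure of error.

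The first comparison asks which parts of the genome carry HP1a. Chromosome 4, a small and largely heterochromatic chromosome, was the most fully covered class, with 85.5% ± 2.4 of its length under clusters in the full lists (SD, n = 2). Assembled heterochromatin followed with 74.8% ± 2.1, unplaced sequence (U alone) with 50.2% ± 6.0 and the Y with 44.1% ± 8.4. The Y here is YHet alone, 0.347 Mb long, so its share need not hold for the whole chromosome. These are shares of the full header length, and stretches where no read could be placed count as uncovered. How much of each class that was is unknown, so a lower share need not mean less HP1a. Among clusters at or above the median value of their list the order of the first 2 was the reverse, with 58.4% of chromosome 4 and 66.1% of assembled heterochromatin covered. The major arms, which hold most of the euchromatin, were covered over 5.63% ± 0.05 of their length. They still held 34.0% ± 1.2 of all covered bases, nearly the same as the 33.9% ± 0.6 in assembled heterochromatin. Most of this arm cover, 60.0% ± 0.9, lay in the 2 Mb of each arm nearest the centromere, so it was not spread along the arms. Each of the other 4 classes exceeded the major arms in both replicates by more than the replicates differed. With 2 libraries an exact paired permutation test cannot go below p = 0.5, so none was used.

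**Figure D1:**
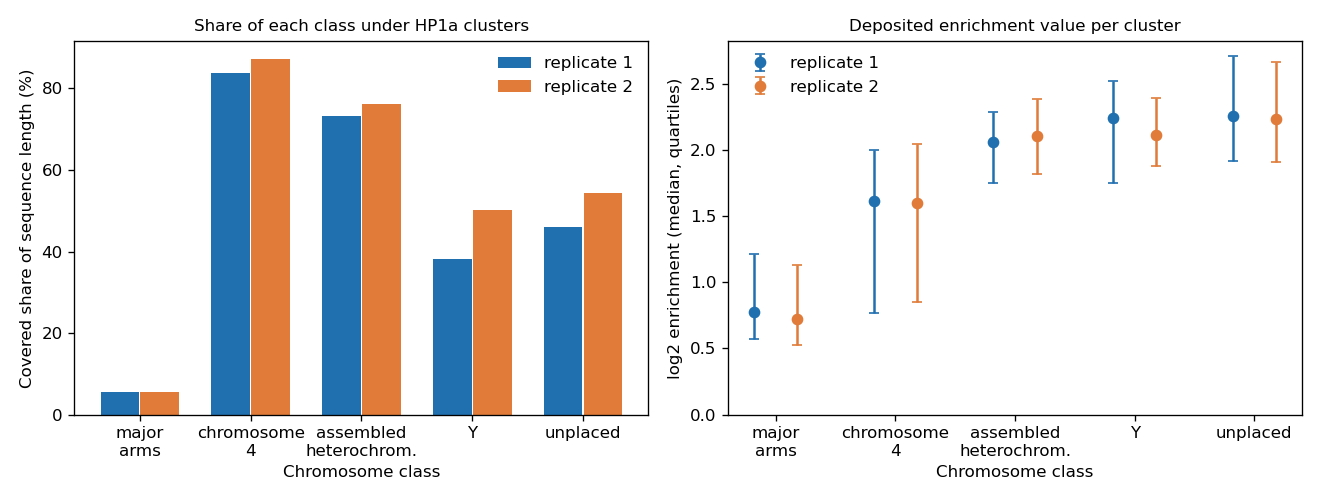
Left, share of the sequence length under HP1a clusters (%) for 5 chromosome classes, with 1 bar per replicate. Right, median deposited log2 enrichment per cluster, with bars from the lower to the upper quartile of the clusters. Chromosome 4 was covered over 83.8% and 87.2% of its length, and the major arms over 5.60% and 5.67%.

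Within assembled heterochromatin, 3LHet was covered over 82.5% ± 2.3, 3RHet over 76.2% ± 2.3, 2RHet over 70.1% ± 1.5, 2LHet over 66.1% ± 3.2 and XHet over 51.7% ± 3.1 (SD, n = 2). The enrichment value of a cluster was also lowest on the major arms, but the other 4 classes came in another order than by cover. Its median on the major arms was 0.78 on the log2 scale in replicate 1 and 0.73 in replicate 2, or 1.71-fold and 1.65-fold. On chromosome 4 it was 1.61 and 1.60, and in assembled heterochromatin 2.06 and 2.11, or 4.17-fold and 4.31-fold. The arm median joined unlike parts. Arm clusters inside the proximal 2 Mb had medians of 1.85 and 1.77, above chromosome 4, and those outside had 0.71 and 0.66. On 3R the medians inside were only 0.78 and 0.73. XHet stood lower than the other assembled heterochromatin, with medians of 1.37 and 1.04. The Y had medians of 2.24 and 2.11. Unplaced sequence had medians of 2.26 and 2.24, but 59.7% and 51.9% of its clusters had a value that another cluster of the list held exactly, against 12.7% and 11% on the major arms. On the Y the share of such repeated values was 57.8% and 55.0%. Without those clusters the cover of unplaced sequence was 34.7% and that of the Y 27.3%, as means of both replicates.

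Along the major arms, HP1a was concentrated at the proximal end of the sequence on 2L, 2R and 3L. The proximal 2 Mb of 2R was covered over 73.0% ± 0.6, that of 3L over 69.0% ± 1.0 and that of 2L over 42.1% ± 1.4 (SD, n = 2). The proximal 2 Mb of X was covered over 11.9% ± 1.5 and that of 3R over 5.05% ± 0.48. Assembled heterochromatin is held in separate sequences, and 3RHet was covered over 76.2% ± 2.3. How far each arm sequence runs into heterochromatin was not examined, so differences between arms cannot be told from differences in the assembly. Over all 5 arms the proximal 2 Mb held 60.0% ± 0.9 of the covered bases, with a cover of 40.2% ± 1.0 inside and 2.46% ± 0.03 outside. The inside share rests mainly on 3 of the arms. On 3R and X, 22.3% ± 2.3 and 19.6% ± 1.7 of the arm's cover lay in the proximal window. Cover there was still above that outside, 5.05% against 1.36% on 3R and 11.9% against 4.76% on X.

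The covered sequence at the proximal end formed long blocks on 2L, 2R and 3L. On 2R an unbroken block of covered 100 kb steps ran from the start of the arm to 1600000, a length of 1.6 Mb. On 3L it ran from 23000001 to the proximal end, at least 1.5 Mb, and on 2L from 22100001 to 23000000, or 0.9 Mb, while the last bases of 2L (23000001 to 23011544) were uncovered in both replicates. On 2R the bins of 500 kb fell from 93.3% and 93.8% covered (1000001 to 1500000) to 15.5% and 16.6% (1500001 to 2000000) in replicates 1 and 2, and the next bin had 24.3% in both. On 3L they fell from 87.1% and 89.6% (23000001 to 23500000) to 3.97% and 3.82% (22500001 to 23000000). On 2L the fall was stepped, from 90.4% and 91.1% (22500001 to 23000000) through 60.5% and 64.7% to 9.89% and 11.4% (21500001 to 22000000). No such block was seen within the arm sequence of 3R, where the first 100 kb was 25.6% and 26.0% covered. On X the strongest bin was not at the end of the sequence but at 21500001 to 22000000, with 35.3% and 40.0%. The 3 widest clusters of replicate 1 lay on 3RHet (1865704 to 1983075), 2R (945953 to 1055955) and 3LHet (348495 to 440631), with values of 2.34, 2.25 and 2.40. Those of replicate 2 lay on 2RHet (382712 to 541520) and on 2R (403018 to 530145 and 1307353 to 1431686), with values of 2.27, 2.38 and 1.91. The other replicate's clusters covered at least 98.4% of each of these 6.

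**Figure D2:**
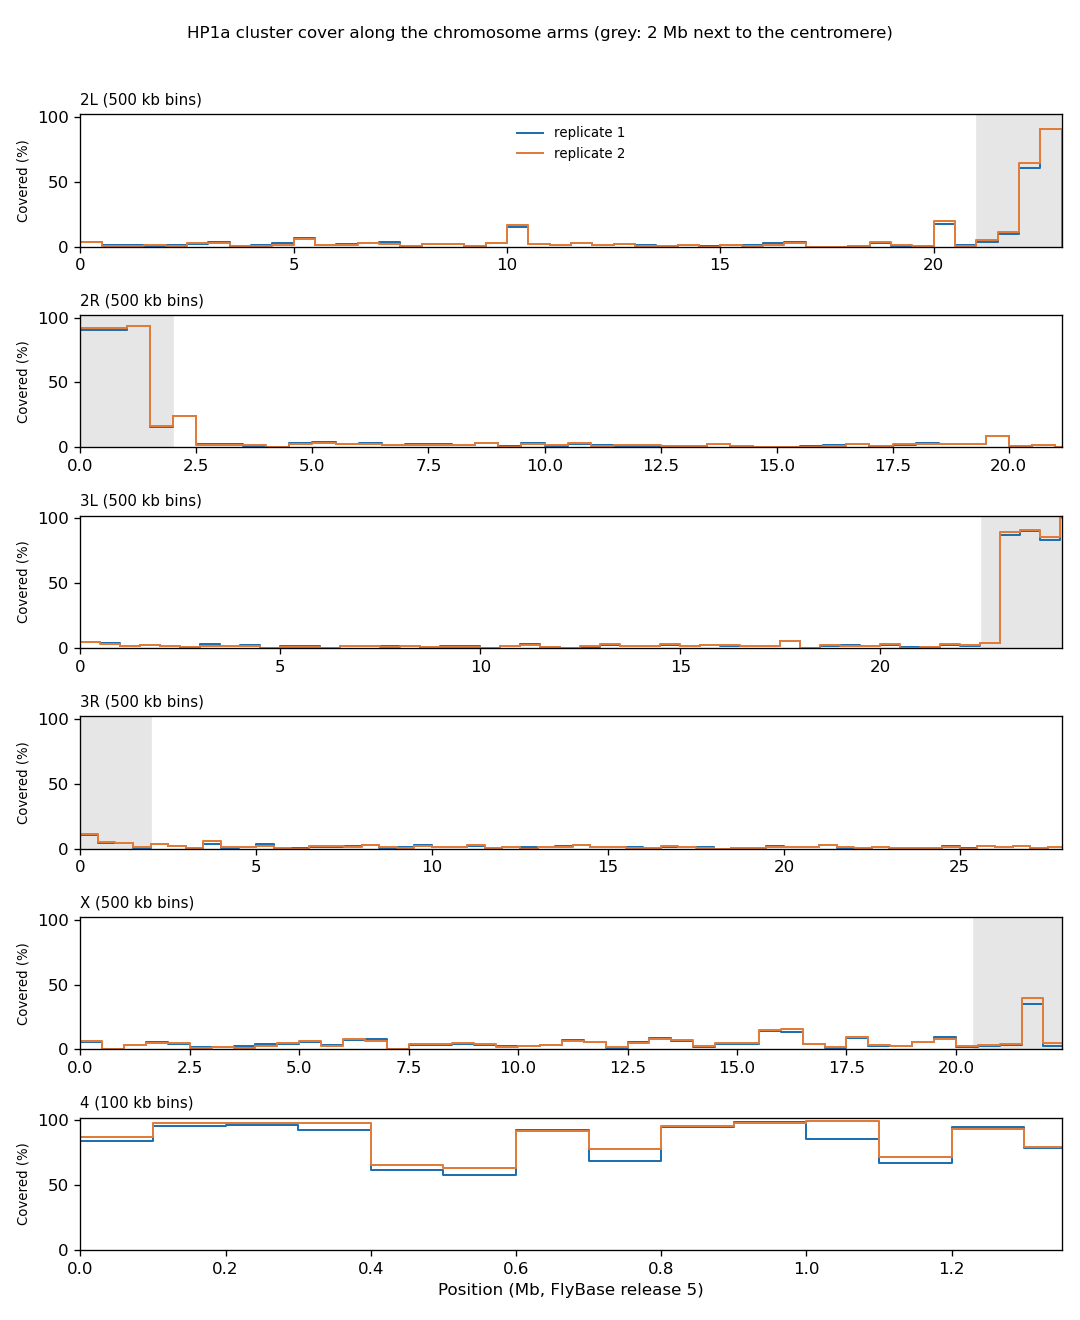
Share of each bin under HP1a clusters (%) against position in Mb on FlyBase release 5, for 5 major arms in bins of 500 kb and for chromosome 4 in bins of 100 kb, with 1 line per replicate and the 2 Mb next to the centromere in grey. Cover rises to about 90% in the proximal parts of 2L, 2R and 3L, is 10.2% and 11.2% in the first bin of 3R, reaches 35.3% and 40.0% in 1 proximal bin of X, and is high along chromosome 4.

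Chromosome 4 was covered over most of its length but not evenly. Of its 14 bins, 7 were at least 90% covered in both replicates. The lowest were 2 neighbouring bins, 400001 to 500000 with 61.5% and 65.5% and 500001 to 600000 with 57.9% and 63.3% in replicates 1 and 2. The bins on either side of this pair had 93.0% and 97.9% (300001 to 400000) and 92.2% in both replicates (600001 to 700000). The bins from 700001 to 800000 (68.5% and 78.2%) and from 1100001 to 1200000 (67.2% and 71.6%) were also lower. The highest mean cover of the replicates was 98.5%, at 900001 to 1000000.

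Outside the proximal 2 Mb the arms carried short and weaker clusters. There were 1090 in replicate 1 and 1066 in replicate 2, with a median width of 2011 bp and 2009 bp and a median value of 0.71 and 0.66. The X had 18.1 ± 0.7 clusters per Mb, against 10.2 ± 0.6 on 2R, 8.42 ± 0.40 on 2L, 7.43 ± 0.28 on 3L and 6.50 ± 0.19 on 3R (SD, n = 2). Its cover was 4.76% ± 0.09, against 2.58% ± 0.08 on 2R, 2.34% ± 0.06 on 2L, 1.66% ± 0.06 on 3L and 1.36% ± 0.05 on 3R. Of the 218 bins of 500 kb that lay outside, 5 were at least 10% covered in both replicates. They were 2L from 10000001 to 10500000 (15.1% and 16.8%), 2L from 20000001 to 20500000 (17.3% and 19.9%), 2R from 2000001 to 2500000 (24.3% in both) and X from 15500001 to 16500000 (14.2% and 15.2%, then 13.8% and 16.0%). The bin on 2R borders the proximal window.

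The widest shared clusters in these outer parts were a pair on 2L. In replicate 1 they spanned 20099484 to 20123275 with a value of 1.61 and 20169885 to 20192657 with a value of 1.57. The matching clusters of replicate 2 had values of 1.49 and 1.77. Other wide clusters lay on 2L from 5158543 to 5174256 (1.36 and 1.35), on 3L from 51081 to 64159 (1.89 and 2.14), on 2R from 19933729 to 19946253 (1.64 and 1.60) and on X from 6445905 to 6457773 (1.65 and 1.44), with the coordinates of replicate 1. At the distal tip of X, 1 cluster spanned 158 to 11593 in replicate 1 and 1 spanned 91 to 20377 in replicate 2. Of the replicate 2 cluster, 87.9% was covered by 2 clusters of replicate 1. Genes under these clusters are not named, because gene coordinates on release 5 were not used here.

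The second comparison asks how far the replicates found the same sites. Of the replicate 1 clusters, 2733 of 3110 (87.9%) overlapped a cluster of replicate 2, and 2483 of 3052 (81.4%) did so in the other direction. Shifted lists gave 49.4% and 47.0% on average, and the permutation p was 0.000999 both times, the smallest that 1000 shifts can give. The Jaccard index was 0.824, against 0.297 in shifted lists (permutation p = 0.000999).

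On the major arms, where little is covered, the overlap was farthest from chance. It was 80.8% and 79.9% of clusters against 10.2% in shifted lists both times. Outside the proximal 2 Mb it was 77.2% and 79.2%, against 5.06% and 5.23%. By arm it ran from 77.0% on X to 84.8% on 2R for replicate 1 and from 72.9% on X to 88.2% on 2R for replicate 2. These parts had adjusted permutation p-values of at most 0.0027. On chromosome 4 the overlap of 93.5% and 82.8% was below the mean of 96.0% and 95.5% in shifted lists (adjusted permutation p = 0.88 and 1). The chromosome was covered over 83.8% and 87.2%, so shifted lists overlap widely too. Why the observed overlap fell below theirs was not tested. The Jaccard index of chromosome 4, 0.935, did exceed the 0.746 of shifted lists (adjusted permutation p = 0.0011). Assembled heterochromatin overlapped by 96.9% and 91.0% against 88.8% and 88.7%, which passed for replicate 1 (adjusted permutation p = 0.0014) and not for replicate 2 (adjusted permutation p = 0.11). Unplaced sequence overlapped by 92.3% and 79.5% against 77.2% and 71.6%, with adjusted permutation p-values of 0.0014 and 0.0027. The Y passed for replicate 1 (86.7%, adjusted permutation p = 0.030) and not for replicate 2 (75%, adjusted permutation p = 0.20). Assembled heterochromatin and the Y both had a Jaccard index above that of shifted lists, 0.926 against 0.604 and 0.551 against 0.278, with adjusted permutation p-values of 0.0011 and 0.0020.

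**Figure D3:**
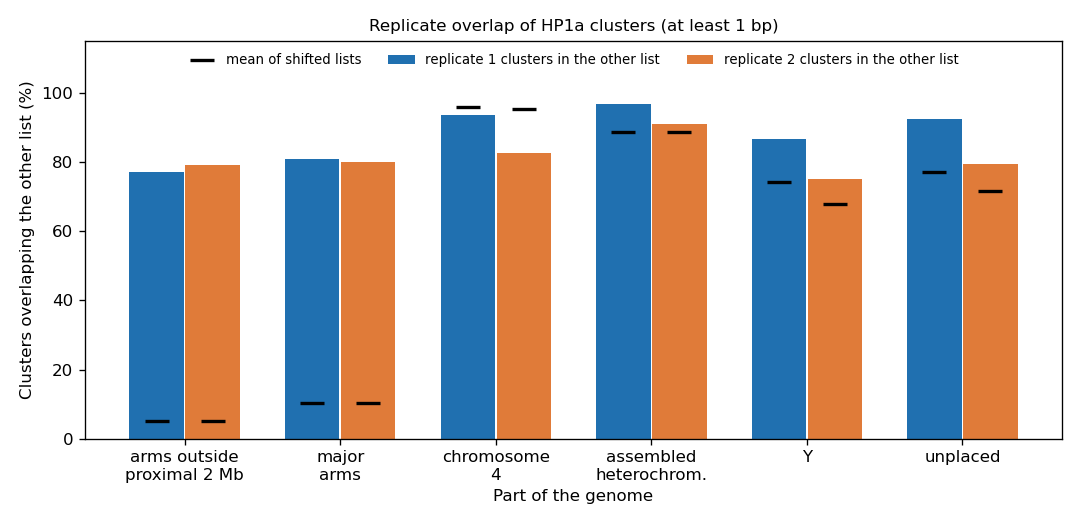
Share of clusters (%) that overlap the other replicate's list by at least 1 bp, for 6 parts of the genome, with 1 bar per replicate and a dash at the mean of 1000 shifted lists. The bars stand far above the dashes on the major arms (80.8% against 10.2% for replicate 1) and below them on chromosome 4.

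Outside the proximal 2 Mb, clusters found in 1 replicate only were weaker and narrower than those found in both. The 249 of replicate 1 had a median value of 0.58 and a median width of 1655 bp, against 0.76 and 2098 bp for the 841 shared ones. The 222 of replicate 2 had 0.60 and 1623 bp, against 0.70 and 2090 bp for the 844 shared ones. The quartiles of the values overlapped, from 0.44 to 0.74 for unshared and from 0.57 to 1.05 for shared clusters in replicate 1. Wider clusters reach an overlap of 1 bp more easily, so part of the gap in width may follow from how sharing was defined.

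The enrichment values of shared clusters ranked alike in both replicates. Over 2733 pairs, the Spearman correlation was 0.894 and Pearson's r 0.894, with a permutation p of 1e-05 each, the smallest that 100000 resamples can give. The Spearman correlation was also computed within the 5 classes. It was 0.928 on the major arms (1124 pairs), 0.817 on chromosome 4 (58 pairs), 0.792 in assembled heterochromatin (498 pairs), 0.637 in unplaced sequence (1014 pairs) and 0.505 on the Y (39 pairs). Pearson's r was 0.943, 0.855, 0.779, 0.631 and 0.454 in the same order. The highest adjusted permutation p was 0.00105 for the Spearman correlation and 0.00403 for r, both on the Y. These are correlations across clusters, which are not independent replicates. Each replicate 1 cluster was paired with the replicate 2 cluster it shared most bases with. The 2733 pairs drew on at most 2483 clusters of replicate 2, so some of those entered more than 1 pair. The median absolute difference between the replicates was 0.11 on the log2 scale on the major arms and 0.26 in unplaced sequence.

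The third comparison sets the series list beside the replicate lists. It held 3891 clusters over 24.8 Mb, 1.25 times as many clusters as replicate 1 and 1.27 times as many as replicate 2. It contained nearly everything found singly, with 99.7% of replicate 1 and 99.9% of replicate 2 clusters overlapping it. Of its clusters, 2028 overlapped both replicates, 317 replicate 1 alone, 447 replicate 2 alone and 1099 neither. The 1099 had a median value of 0.52 and a median width of 1367 bp, against 1.75 and 4266 bp for those in both. The narrowest cluster of the series list was 1001 bp wide, against 1301 bp in both replicate lists. Part of the gap in width may therefore reflect an unlike lower limit, and wider clusters also reach an overlap of 1 bp more easily. The gap in value differed by class. On the major arms the medians were 0.44 in neither and 0.71 in both. In assembled heterochromatin they were 2.24 and 2.08, and in unplaced sequence 2.19 and 2.15. On chromosome 4 they were 0.40 in neither (10 clusters) and 1.81 in both (27 clusters), and on the Y 1.48 (4 clusters) and 2.03 (24 clusters). Most of the 1099 in neither, 774, lay on the major arms, where they made up 34.0% of the list. The share was highest on X, with 328 of its clusters (40.3%), and ran from 27.4% on 2R to 32.4% on 3R on the other arms. The classes kept the order they had in the replicates, with chromosome 4 covered over 91.8%, assembled heterochromatin over 81.2%, unplaced sequence over 70.5%, the Y over 67.4% and the major arms over 7.56%.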

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

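Of 69 alternative values, 38 moved by less than the replicate spread or, for counts, by less than 1.5 times, or stayed past the same test threshold. Leaving out either replicate always moves the mean of both by less than their SD, so those values could not move by this rule. A cut at the median likewise fixes the number of clusters. The tally is therefore not a measure of robustness. The overlaps, Jaccard index and Spearman correlation over all sequences stayed past the threshold under each alternative run, and no alternative was run for the overlap within single classes. The cover of a class moved with how much was called, while the major arms stayed below each other class in every setting run. At or above the median value, 1555 clusters were left in replicate 1 and 1526 in replicate 2, over 14.68 Mb on average, and cover was 2.94% on the major arms, 58.4% on chromosome 4, 66.1% in assembled heterochromatin and 43.3% in unplaced sequence, so that chromosome 4 fell below assembled heterochromatin. Without unplaced sequence, 2012 and 1908 clusters and 14.70 Mb remained. With the series list, cover in the order of major arms, chromosome 4, assembled heterochromatin, Y and unplaced was 7.56%, 91.8%, 81.2%, 67.4% and 70.5%. Leaving out clusters with repeated values, a setting chosen after seeing the data, gave 5.32%, 69.9%, 27.3% and 34.7% for the same order without chromosome 4. With a proximal window of 1 Mb the cover was 56.9% inside and 3.39% outside, and 42.4% of the arms' cover lay inside. With 5 Mb these were 18.3%, 2.26% and 68.2%. In the series list, with 2 Mb, they were 44.6%, 4.16% and 49.6%. With clusters found in both replicates alone, also chosen after seeing the data, cover outside 2 Mb was 2.10%, and 63.4% of the arms' cover lay inside. The alternatives for gene lists and gene features were not run. No paired analysis was possible because the inputs entered only through the lists called against them. Depth per library is unknown, so it cannot be said how many weak clusters on the arms were missed.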

Other observations

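The tests of the chromosome ends, of the median bins of X and of repeated values were chosen only after the result was seen, as were the settings tried on the X ratio. The predictions for the other 2 tests on X were set before their values were computed. The bounds for the chromosome ends and the repeated values are also not the first ones. The ends were first asked to stand out on at least 4 of 5 arms against at most 1, and 90% of repeated values were first asked to be small fractions. Neither first bound gave a verdict, and both were rewritten with the results in view, after 5 fraction limits had been tried.

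The distal 100 kb of the arms differed in HP1a cover. On 3L it was 16.8% and 17.0% covered in replicates 1 and 2, above 99.6% of the arm's other 100 kb bins outside the proximal window. On X it was 22.7% and 25.1%, above 98% and 97.5% of the other bins. On 2L (4.28% and 4.61%) and 3R (2.27% and 2.42%) it stayed under the 95th percentile of the other bins, and on 2R no base of it was covered in either replicate. The hypothesis that every distal end is covered above the rest of its arm was not borne out, since 2 of 5 arms passed in both replicates. On both of these arms much of the cover lay under 1 cluster. On 3L it was 13.1 kb and 12.8 kb wide in replicates 1 and 2, and it started at 51081 in replicate 1. At the tip of X it was 11.4 kb and 20.3 kb wide. How far the assembled sequence reaches into each telomere was not examined.

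Outside the proximal 2 Mb, the X arm was covered 2.37 times as much as the autosomal arms in replicate 1 (4.69% against 1.98%) and 2.55 times as much in replicate 2 (4.82% against 1.89%). It exceeded the highest autosomal arm, 2R, in both (2.63% and 2.53%). Across 40 bins of X and 178 autosomal bins of 500 kb the two-sided permutation p was 1e-05 in each replicate, the smallest that 100000 resamples can give. Neighbouring bins are not independent, and taking the arm as the unit the smallest one-sided p is 0.2. The tables argue against 2 technical explanations as the whole cause. Weak calls near the threshold would lower the ratio among strong clusters. It was 2.38 and 3.40 at or above the median of the list, 1.79 in both, which kept only 14 and 16 clusters on X and 28 and 25 on autosomes. With the cut at the median of these arm clusters, 0.71 and 0.66, it was 3.37 and 3.47, with 243 and 245 clusters on X and 302 and 288 on autosomes. X clusters had higher median values than autosomal ones, 0.80 against 0.64 in replicate 1 and 0.76 against 0.60 in replicate 2. Anything that raised values on X as a whole would pass these cuts too, so they speak to weak calls alone. A few strongly covered stretches of X would leave the median bins alike, and they differed by 2.76 and 3.12 times. The ratio was 2.41 with clusters found in both replicates, 2.80 in the series list and 2.74 with 5 Mb left out at the proximal end. Values resting on few reads also stay open, since only 14.2% and 12.1% of these X clusters had repeated values and leaving such clusters out could not have moved the ratio far. So does read depth on X, which may differ from the autosomes where male larvae are present, and so do repeats specific to X. The lists hold neither read counts nor sequence, and no biological explanation was tested.

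Repeated values were commonest in unplaced sequence and on the Y. In replicate 1, 984 clusters (31.6%) had a value that another cluster held to 9 decimals, and in replicate 2, 860 clusters (28.2%). A candidate explanation is that these are log2 ratios of small whole numbers. The rewritten bound asked for more than 50% of them, with under 5% of random values. Of the 262 and 236 values so held, 80.2% and 86.0% differed from the commonest one by the log2 of a fraction with numerator and denominator up to 72, within a relative tolerance of 1e-06. Of 10000 random values in the same range, 0.17% and 0.15% did, and of values held by 1 cluster, 15.7% and 16.7%. The share of clusters with repeated values was 59.7% and 51.9% in unplaced sequence, 57.8% and 55% on the Y, 23.5% and 20.5% in assembled heterochromatin and 12.7% and 11% on the major arms. The fraction test took all classes together, so whether clusters of any 1 class rest on few reads stays open. The reads themselves were not examined.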
